A study of Mus musculus with 10 samples.

How the data were processed

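Mouse C2C12 myoblasts received either a synthetic miR-142-3p or a scrambled control RNA at 150 nM with a lipid reagent, and 150 ng of RNA taken after 72 hours was labelled with Cy3 and hybridised to a 1-colour Agilent oligonucleotide array, per the labels' protocols. Each deposited scanner file holds spot intensities on a linear scale, made with Feature Extraction 12.0.0.7 per the file headers, while the submitters' processing notes name version 10.7.3.1. The array has 62976 spots, of which 59305 are not controls and hold 55681 different probes of 60 bases, and the headers give the mm9 build. The deposited series matrix holds intensities too. Its scale was found to be linear and its values tracked each scan's log2 signal at r of at least 0.997. It lists values for only 18807 to 24051 probes per sample, none of them a probe marked as not significantly over background, with column medians between 177.5 and 356.3. The same maximum of 465700 occurs in each column, and what between-array step gave this was not given in the sources used here. All 10 files and all columns were mapped to samples.

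The main signal was log2 of the processed signal, which the scanner software had already corrected for background and spatial trend, minus the scan's 75th percentile over non-control probes. Spots marked as non-uniform or population outliers were left out and spots of 1 probe were averaged. A probe was kept when it was well above background on at least 4 of the 10 scans, a probe counting as such when at least 0.5 of its spots did. This left 17455 probes. The probe with the highest mean over all scans stood for its gene, which gave 13677 genes. At most 34.6% of the spots of a scan were well above background, so a percentile over probes well above background on all 10 scans was added as an alternative. Gene names were updated through RefSeq tables of assembly GRCm38.p6, with 28026 probes matched by accession, 3418 by symbol and 295 by synonym, and 23942 keeping the name in the file. No coordinates of that assembly were used. Of 2888 genes with more than 1 kept probe 240 were called, and in 14 of these another probe had the opposite sign.

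The labels name 6 mimic and 4 scramble replicates, and the analysis chosen before the data were examined treated these as 10 samples. The headers put them on 1 slide, 5 array positions and 2 scan days. Mimic replicates 1 and 4, 2 and 5, and 3 and 6, and scramble replicates 1 and 3, and 2 and 4, share a position. Because a rescan would be no new replicate, the scans of a position were averaged, a choice made after the positions were seen, and the 10-sample fit became an alternative. Nothing in the headers says from which culture the RNA of a position came, so p-values measure the spread between these 5 arrays, which may be partly technical. The pairs of replicate numbers across groups were checked through the correlation of deviations from group means, which lay between −0.28 and 0.19. No scramble scan correlated best with the mimic scan of its own number. Each correlated best with a mimic scan of its own scan day, so the check cannot tell whether the numbers mark shared cultures. The labels do not say that they do, and the numbers were not taken as pairs.

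Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (3 residual and 5.26 prior degrees of freedom) with Benjamini-Hochberg adjustment over all genes, and a threshold of 0.05. Confidence limits are 95% limits from the same fit. Lists fixed before the data were examined, 26 in all, were tested with camera where at least 5 genes were measured, with a correlation of 0.01 between genes, and again with an estimated correlation and with fry; adjusted p-values of lists run over 24 lists. The result of 1 list is not reported here. Where a probe was not well above background on any scan of a group, only a bound is given, except for the fitted differences of gene families. The bound sets the mean of the brighter group against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. Of genes given with a fold, some were well above background on only part of a group's scans: besides those said in the report, Myog and Fgf21 on 5, and Itgav, Srebf1 and Tnrc6b on 4 of 6 mimic scans, and Chil5, Lum and Sdf2l1 on 3 and Pdk1 on 2 of 4 scramble scans. No more than 1 spot of a scan was saturated.

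The genes named are the 10 rises and 10 falls with the largest fitted difference among called genes with a gene symbol whose groups do not overlap, up to 4 genes of each list in order of p, and 10 genes fixed before the data were examined (Rac1, Rock2, Adcy9, Fndc3b, Myod1, Myog, Cdkn1a, Mki67, Plin2 and Cpt1b). A gene named for another reason is said to be so. On simulated data for this comparison (13630 genes, 200 of them changed, 20 runs) the fit recovered 88.3% of genes changed 4-fold. It recovered 7.91% of those changed 2-fold and 0.15% of those changed 1.5-fold, with 5.70% of calls false. These runs gave 67.55 calls on average against 1332 in the data, where the adjusted threshold is therefore less strict. The shares recovered do not carry over to the data. Camera found a list of 20 genes raised 2-fold in 20 of 20 runs, and 2.55% of unmoved lists had a p under 0.05. The simulated genes varied independently, so this rate does not cover lists whose genes vary together. In the data the estimated correlation was 0.21 in the myogenic differentiation list and 0.34 in the DNA replication list.

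Alternatives covered 4 other between-array scalings, normexp background correction with an offset of 50, the series matrix values, filters, probe summaries, variance models, blocks and left-out scans or arrays. Searches for seed sites in 3' untranslated regions and among all 7-base words there were planned but not run, because transcript sequences were not used here. Signal over background and the number of arrays set the precision, and no transcript level of the microRNA itself was analysed here. Python 3.11.15 with pandas 2.3.3 read the files.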

Results

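Gene expression was measured in C2C12 cells, a mouse myoblast line that can be induced to differentiate into multinucleated myotubes, after transfection with a mimic of the microRNA miR-142-3p or with a scrambled sequence. Both were used at 150 nM, the transfection efficiency was given as about 60%, and RNA was taken 72 hours later. The labels list 6 mimic and 4 scramble samples and describe them as separate transfections. The titles of all 4 scramble samples and of no mimic sample carry a re-analysis remark, whose meaning is not given in the sources used here. The 10 scans behind these samples came from 5 array positions of 1 slide, each scanned on 2 days, with 3 positions for the mimic and 2 for the scramble. Scans of the same position shared between 24 and 82 spots marked non-uniform, whereas no other pair shared more than 2. The signals of same-position scans correlated at r = 0.984 to 0.990 over 11141 bright spots, and no other pair exceeded 0.977. The deviations of spots from the mean of their probe, over 1334 spots, did not part the pairs: same-position scans correlated at 0.641 to 0.884 and other pairs at up to 0.690. Since the headers give them 1 position, the 2 scans of a position were averaged and counted as 1 sample, so that n = 3 mimic arrays and n = 2 scramble arrays. Between 25.4% and 34.6% of the 59305 non-control spots of a scan were well above background.

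**Figure D1:**
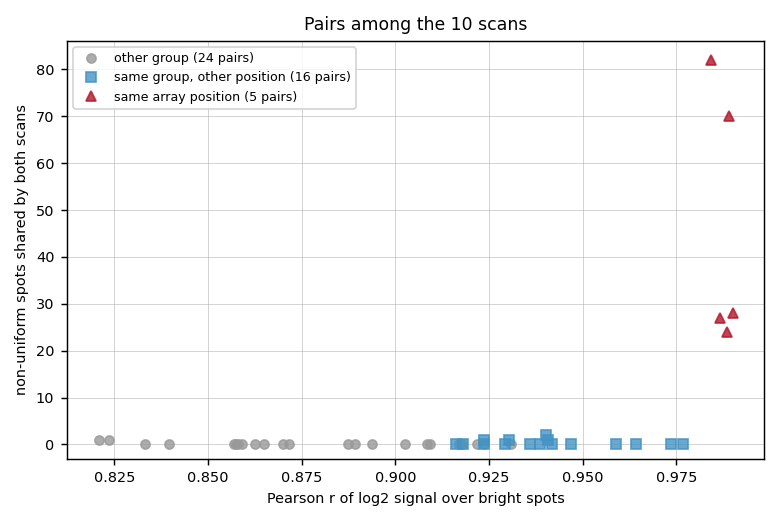
All 45 pairs among the 10 scans, with the correlation of log2 signal over bright spots (no unit) on the horizontal axis and the number of spots marked non-uniform in both scans on the vertical axis. The 5 pairs from 1 array position share 24 to 82 such spots, and the 40 other pairs share at most 2.

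The comparison of mimic with scramble asks which transcripts change when miR-142-3p is raised in myoblasts. The largest changes were falls of muscle differentiation genes such as Myog, Actc1 and Tnnc1, and rises of single genes such as Slurp1, Chil5 and Cd68. Myog, the transcription factor that drives terminal myogenic differentiation, fell 135-fold, from a normalised log2 signal of 6.45 ± 0.30 (SD, n = 2) in the scramble to −0.62 ± 0.21 (SD, n = 3) in the mimic (limma, adjusted p = 1.14e-05). Its probe lies on chromosome 1 at 136188874 to 136188933 in the mm9 coordinates of the files. The 10 falls and 10 rises described first were picked by the fitted difference among called genes whose groups do not overlap, a rule fixed in advance. Genes with only a bound have no settled rank among them. The other falls picked were those of the sarcomere genes Myom3, Actc1, Lmod3, Tnni1, Tnnc1 and Myh3, the sarcoplasmic calcium-binding protein gene Casq2, the muscle kinase gene Srpk3 and the hormone gene Fgf21. Actc1 fell 41.4-fold and Fgf21 26.7-fold. Lmod3 and Tnni1 were well above background on 3 of 6 mimic scans and Tnnc1 on 1, while Myom3, Casq2 and Srpk3 were not well above background on any mimic scan and were at least 39.9-fold, 13.0-fold and 7.32-fold lower.

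The 10 rises with the largest fitted difference were those of Sprr2e, Slurp1, Chil5, Cd68, Selp, Serpinb9g, Hdc, Serpinb9f, Sprr1a and Prl2c5. Sprr2e and Sprr1a encode components of the cornified envelope of squamous epithelium, Cd68 a lysosomal protein of macrophages, Selp the adhesion molecule P-selectin and Hdc the enzyme that makes histamine. Chil5 rose 36.5-fold, Cd68 28.5-fold, Sprr1a 16.4-fold and Prl2c5 16.3-fold. The array holds 2 probes of Cd68, of which only 1 was kept. The other was well above background on fewer than 4 of the 10 scans, so this rise rests on 1 probe. The other 6 were not well above background on any scramble scan, and rose at least 20.4-fold for Slurp1, 10.2-fold for Hdc, 8.79-fold for Sprr2e, 7.22-fold for Serpinb9f, 6.74-fold for Selp and 5.13-fold for Serpinb9g. Serpinb9f, Serpinb9g, Prl2c5 and the Sprr genes have close paralogs that can share a probe, so the member that rose is uncertain. The probe of Cd68 lies on chromosome 11 at 69477775 to 69477834 and that of Prl2c5 on chromosome 13 at 13283943 to 13284002.

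**Figure D2:**
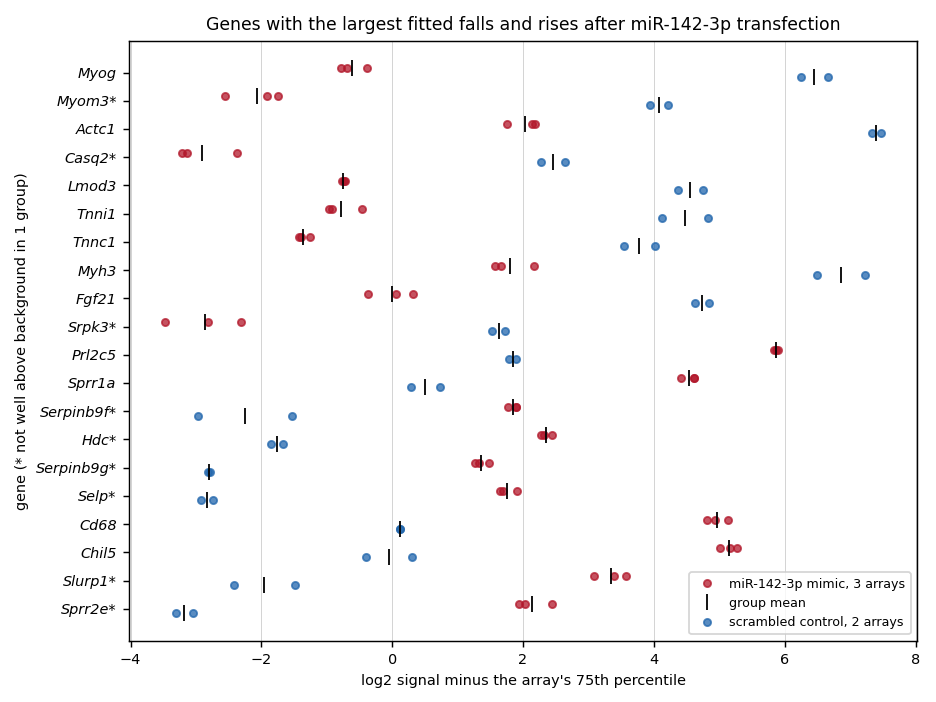
Log2 signal minus the array's 75th percentile (horizontal axis) for the 10 falls and the 10 rises with the largest fitted difference (vertical axis), with 1 point per array and a bar for each group mean. The 3 mimic arrays of Myog average −0.62 and the 2 scramble arrays 6.45. Only called genes whose groups do not overlap could be picked. An asterisk marks a gene not well above background in 1 group.

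In all, 1332 of 13677 genes differed at an adjusted p below 0.05 (limma), of which 802 were higher and 530 lower with the mimic. By the fitted difference all changed by at least 1.5-fold. Of these calls 1145 carried a gene symbol. Fitted differences of at least 4-fold comprised 161 rises and 153 falls, a count that includes genes with only a bound. Such genes made up 215 of the higher and 64 of the lower calls, and some of their bounds lie below 4-fold. The filter of at least 4 scans favours the former. A gene seen only in the mimic could pass on 4 of 6 scans, while one seen only in the scramble needed all 4. An unadjusted p below 0.05 (limma) was reached by 3456 genes. The split between rises and falls depended on the filter and on the scaling. Without a filter 205 genes were higher and 202 lower, and among genes well above background on all 10 scans 636 were higher and 375 lower. With the 75th percentile taken over probes well above background on all 10 scans, 674 genes were higher and 664 lower. The median log2 difference of all genes was 0.09 with the first scaling and −0.04 with the second. Scans of the first day alone gave 1284 changed genes and those of the second day 940. A fit to all 10 scans with scan date as a block and array as a random block gave 1796. Scaling to the array median gave 761, the fits without mimic array 1, 2 or 3 gave 641, 672 and 668, that without scramble array 1 gave 3671, and without a filter 407 of 34607 genes changed. The groups did not overlap for 42.6% of all genes tested, against 20% by chance with 3 arrays against 2. The 2 scramble arrays were not equally far from the mimic. Over genes, scramble array 1 correlated with the mimic arrays at r = 0.946 to 0.951 and scramble array 2 at 0.917 to 0.926.

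Of the 29 measured genes of the myogenic differentiation list, 24 fell and none rose, with 28 falling when adjusted over the list alone. The median log2 difference was −3.14, or −3.07 with genes below background set at their bound (camera, adjusted p = 5.68e-38; adjusted p = 0.257 with an estimated correlation). It was −2.84 on the first scan day and −3.32 on the second, and −3.14 with the date as a block. Besides Myog, Actc1 and Tnnc1, slow skeletal troponin T (Tnnt1) fell 19.3-fold, by 4.27 ± 0.21 (SE) on the log2 scale. The myoblast identity list moved both ways, with 7 of 13 measured genes lower and 2 higher and the same counts adjusted over the list alone (median −0.74, camera adjusted p = 0.00837; adjusted p = 0.405 with an estimated correlation). Its median was −0.76 on the first day and −0.72 on the second, and −0.27 over its genes on the array without a filter. Myod1, the myogenic determination factor, fell 9.51-fold (log2 difference −3.25 ± 0.28 SE), the muscle cadherin gene Cdh15 fell 3.94-fold, Six4 fell 2.34-fold (a call lost with scaling to the array median and without a filter) and Fgfr4 was at least 2.33-fold lower. The rises were those of Cd34 and Met, both named after their values were seen.

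Of 16 measured genes reported elsewhere as miR-142-3p targets, 4 fell and none rose. Adjusted over the list alone, 5 fell and 1 rose. The median was −0.41 (camera, adjusted p = 0.00280; adjusted p = 0.470 with an estimated correlation and 0.0549 with fry), with −0.34 on the first scan day, −0.46 on the second and −0.25 without scramble array 1. Cfl2, the muscle form of the actin-severing protein cofilin, fell 4.73-fold (−2.24 ± 0.22 SE, adjusted p = 0.000432). Il6st, the gp130 receptor subunit, fell 3.45-fold, Wasl, an activator of actin nucleation, fell 2.67-fold (lost without a filter and with the mean of a gene's probes), and the integrin gene Itgav fell 2.15-fold. The call for Itgav was lost in 7 of 33 settings: scaling to the array median, normexp background, no filter, the first scan day, and without mimic array 1, mimic array 3 or scramble array 2. Among the genes fixed for reporting, Rac1 had a log2 difference of 0.73 ± 0.23 (SE, adjusted p = 0.0951) and its other probe had the opposite sign. Adcy9 had −0.45 ± 0.20, Rock2 0.28 ± 0.22 and Fndc3b 0.14 ± 0.25, none past the threshold.

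Cell division genes rose: 11 of 22 measured were higher and none lower, and 17 were higher when adjusted over the list alone (median 0.82, camera adjusted p = 3.96e-07; adjusted p = 0.378 with an estimated correlation). The median was 0.85 on the first day and 0.78 on the second. Cyclin B2 (Ccnb2) rose 2.46-fold, the kinetochore motor Cenpe 2.54-fold, the anaphase activator Cdc20 2.04-fold and the spindle protein Prc1 1.97-fold, with adjusted p between 0.0181 and 0.0357; these calls were lost in 4, 7, 8 and 11 of 34 settings, each without a filter and without any 1 of the 3 mimic arrays, and all but that of Ccnb2 without scramble array 2, where Cenpe had 0.85 in place of 1.35. Mki67 had a log2 difference of 0.52 ± 0.19 (SE, adjusted p = 0.135). In the DNA replication list 2 of 25 genes rose and 1 fell, and 4 rose and 1 fell when adjusted over the list alone (median 0.53, camera adjusted p = 0.00448; adjusted p = 0.685 with an estimated correlation and 0.119 with fry). Its median was 0.62 on the first day and 0.49 on the second. Pola1, a subunit of DNA polymerase alpha, rose 2.36-fold, thymidine kinase Tk1 rose 2.25-fold and E2f2 fell 2.22-fold, while Rfc4 had 1.02 ± 0.27 (adjusted p = 0.0538). The call for E2f2 was lost in 7 of 34 settings, among them the fits without any 1 mimic array, and its value moved from −1.15 to −0.70 without scramble array 1. That for Pola1 was lost with normexp background, without a filter and without mimic array 3, and that for Tk1 with scaling to the array median and without a filter. Cdkn1a, the inhibitor of cyclin-dependent kinases, fell 3.13-fold (adjusted p = 0.00282; lost without a filter). It was the only change among 17 genes of the p53 and cell-cycle arrest list, where 2 genes fell when adjusted over the list alone (camera, adjusted p = 0.722, median 0.04, mean −0.03).

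Of 12 measured interferon response genes 6 rose and none fell, with 8 rising when adjusted over the list alone (median 1.16, or 1.13 at the bounds; camera, adjusted p = 5.27e-06; adjusted p = 0.324 with an estimated correlation). The median was 1.19 on the first day and 1.13 on the second, 0.60 over genes well above background on all 10 scans, and 0.36 over the list's genes on the array without a filter (adjusted p = 1.16e-06). Oasl2 was at least 3.28-fold, the chemokine gene Ccl5 at least 2.28-fold and the guanylate-binding protein gene Gbp2 at least 2.25-fold higher, and Isg15, a ubiquitin-like modifier, rose 2.33-fold, a call lost without a filter. The other 22 of the 34 genes of this list were not kept, because fewer than 4 scans were well above background. In the leukocyte list 2 of 5 measured genes rose, Cd68 and the lipopolysaccharide co-receptor gene Cd14 (2.90-fold; lost without a filter), and none fell, as when adjusted over the list alone (median 0.17, mean 1.36, camera adjusted p = 0.0210; adjusted p = 0.404 with an estimated correlation). Its median was 0.28 on the first day and 0.17 on the second, and between 0.04 and 0.44 over all settings, and the call was lost without a filter (median 0.04, adjusted p = 0.250), with the mean of a gene's probes (adjusted p = 0.0548) and without scramble array 1 (adjusted p = 0.164). Itgam had a log2 difference of 0.15 ± 0.19 and Csf1r 0.17 ± 0.24, and the other 11 leukocyte markers, among them Ptprc, Lyz2 and Tyrobp, were not well above background on any scan.

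No metabolic list passed the threshold in camera in the main fit, though some of their genes changed. In glycolysis 5 of 21 genes rose and none fell, with the same counts adjusted over the list alone (median 0.26, camera adjusted p = 0.0905). Aldolase C (Aldoc) rose 2.92-fold, the glucose transporter gene Slc2a1 2.32-fold, hexokinase 2 (Hk2) 2.05-fold and Pdk1, an inhibitor of pyruvate dehydrogenase, 1.83-fold. These calls were lost in 6 of 34, 7 of 34, 10 of 34 and 14 of 33 settings, each without a filter, with the slide row as a block, without any 1 mimic array and without scramble array 2. In the last of these Aldoc had 0.95 in place of 1.55, Slc2a1 0.80 in place of 1.21 and Hk2 0.69 in place of 1.04. In fatty acid oxidation 2 of 27 genes fell and none rose, in both counts (camera, adjusted p = 0.404, median 0.02, mean −0.17): the mitochondrial uncoupling proteins Ucp2, at least 3.30-fold lower, and Ucp3, at least 2.28-fold lower. Cpt1b, the muscle carnitine palmitoyltransferase, had a log2 difference of 0.17 ± 0.31 and Cpt1a 0.63 ± 0.19. In lipid synthesis and storage 3 of 22 genes rose and 3 fell, in both counts (camera, adjusted p = 0.752, median 0.02). Abhd5, a co-activator of triglyceride lipase, rose 2.10-fold with 1 of 2 other probes opposite in sign (a log2 difference of 1.07, but 0.31 and no longer past the threshold with the mean of a gene's probes), Agpat2 rose 1.77-fold, and the lipogenic regulator Srebf1 and the triglyceride synthase Dgat2 fell 2.32-fold and 2.07-fold. These calls were lost in 9 of 34 settings for Abhd5, 16 of 34 for Agpat2, 16 of 33 for Srebf1 and 10 of 34 for Dgat2, among them the fits without mimic array 1 or without mimic array 3 for each. The lipid droplet protein gene Plin2 had 0.58 ± 0.22 (adjusted p = 0.142). The tricarboxylic acid cycle list had 1 rise among 23 genes in both counts, the pyruvate dehydrogenase kinase gene Pdk4 (2.02-fold; lost in 8 of 34 settings, among them those without mimic array 2, mimic array 3 or scramble array 2), with a median of −0.23 (camera, adjusted p = 0.0872). The oxidative phosphorylation list had 1 fall among 47 genes, cytochrome c1 (Cyc1, 1.72-fold; lost in 10 of 34 settings, among them those without any 1 mimic array or scramble array 2), and none when adjusted over the list alone (median 0.03, camera adjusted p = 0.528). Glycogen metabolism had 1 rise among 17 genes in both counts, the branching enzyme gene Gbe1 (2.19-fold; lost in 8 of 34 settings, among them those without any 1 mimic array or scramble array 2; camera, adjusted p = 0.752, median −0.04, mean 0.06). None of 24 sterol genes changed in either count (camera, adjusted p = 0.192, median −0.12).

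**Figure D3:**
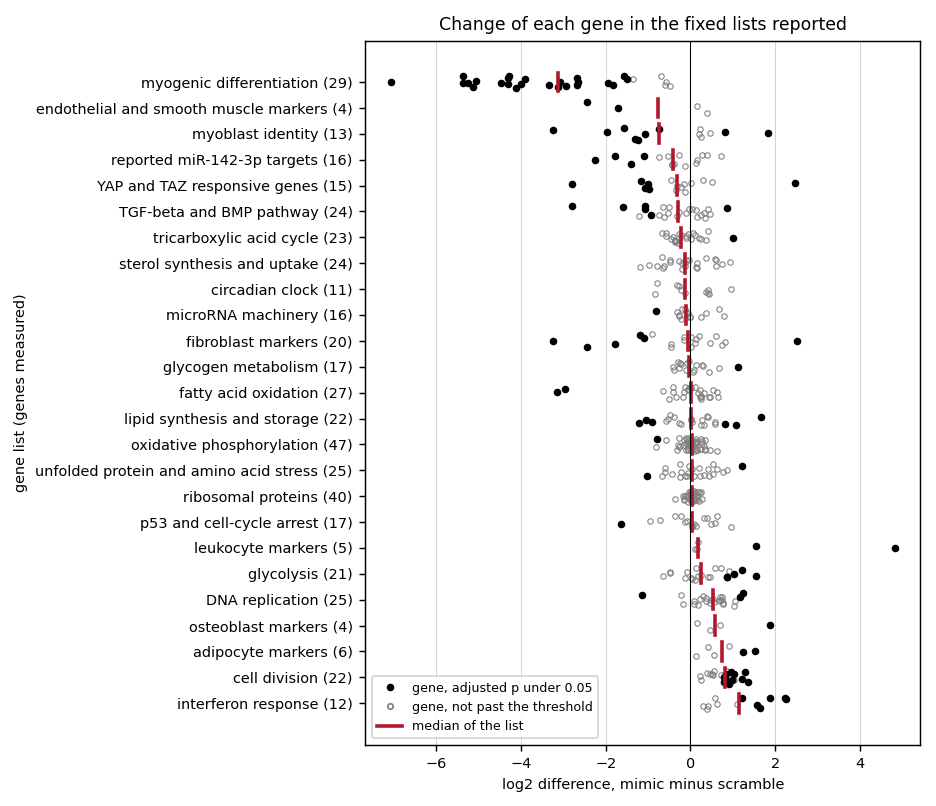
Log2 difference of mimic minus scramble (horizontal axis) for each measured gene of the lists reported (vertical axis, number of genes measured in parentheses), with filled points for an adjusted p under 0.05 and a bar at each median. The myogenic differentiation list lies lowest, with a median of −3.14, and the interferon list highest, with 1.16.

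In the TGF-beta and BMP list 5 of 24 genes fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone (median −0.29, camera adjusted p = 0.00448; adjusted p = 0.470 with an estimated correlation and 0.0675 with fry). Its median was −0.26 on the first day and −0.33 on the second, with −0.18 without a filter and −0.55 without scramble array 2, and the call was lost without scramble array 1 (median −0.11, adjusted p = 0.0952). The secreted factor gene Ccn2 was at least 4.49-fold lower, Bmp4 fell 3.00-fold, and Acvr2a and Tgfb2 fell 2.11-fold and 2.11-fold. Acvr2a was well above background on 1 of 6 mimic scans and its call was lost in 8 of 33 settings, among them those without any 1 mimic array. That for Tgfb2 was lost in 7 of 34, among them those without mimic array 2, mimic array 3 or scramble array 2. The list of YAP and TAZ responsive genes, which shares Ccn2 and Tgfb2, had 5 falls and 1 rise among 15 genes in both counts (median −0.32, camera adjusted p = 0.00837; adjusted p = 0.405 with an estimated correlation), medians of −0.38 and −0.29 on the first and second day, and −0.20 without mimic array 3. Tissue factor (F3) fell 2.26-fold, a call lost in 4 of 34 settings, among them those without mimic array 1 or 3, and Wwc1 was at least 2.24-fold higher. Of 20 fibroblast genes 5 fell and 1 rose, and 5 fell and 3 rose when adjusted over the list alone (camera, adjusted p = 0.0872, median −0.07, mean −0.31). Periostin (Postn) was at least 3.11-fold lower, Loxl1 fell 2.26-fold (lost with scaling to the array median and without a filter) and Fap passed the threshold as lower, but was well above background on only 1 of 6 mimic scans and had a log2 difference between −2.92 and −1.14 over the settings. The proteoglycan lumican (Lum) rose 5.72-fold, by 2.51 on the log2 scale, with 1.73 without scramble array 2 and 3.30 without scramble array 1. Of 4 measured endothelial and smooth muscle genes, too few for a list test, smooth muscle actin (Acta2) fell 5.46-fold and Tagln 3.27-fold in both counts, the latter lost without a filter, with Kdr and Smtn at 0.38 ± 0.23 and 0.16 ± 0.21. Of 6 measured adipocyte genes 2 rose in both counts, the regulators Cebpd (2.87-fold) and Pparg (2.36-fold), both lost without a filter, with a median of 0.74, or 0.48 at the bounds (camera, adjusted p = 0.0210; adjusted p = 0.404 with an estimated correlation). Their median was 0.89 on the first day, 0.58 on the second and 0.43 with normexp background, and the call was lost without a filter (median 0.04, adjusted p = 0.250) and without scramble array 1 (adjusted p = 0.101). Of 4 measured osteoblast genes Phex rose 3.65-fold, and 2 rose when adjusted over the list alone.

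None of the remaining lists passed the threshold in camera in the main fit, a test that can miss changes going both ways. None of 40 ribosomal protein genes changed in either count (median 0.04, camera adjusted p = 0.752), nor any of 11 circadian clock genes (camera, adjusted p = 0.722, median −0.12, mean 0.00). Among 25 genes of the unfolded protein and amino acid stress list, Sdf2l1 rose 2.32-fold and the amino acid transporter gene Slc7a5 fell 2.04-fold in both counts (camera, adjusted p = 0.977, median 0.04), and the calls were lost in 9 of 33 and 9 of 34 settings, among them those without a filter, without any 1 mimic array or without scramble array 2. Among 16 genes of the microRNA machinery, Tnrc6b, a partner of Argonaute, fell 1.77-fold, a call lost in 18 of 33 settings, among them the fits without any 1 mimic array or scramble array 2, and none passed when adjusted over the list alone (camera, adjusted p = 0.417, median −0.10).

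Of the 24 lists large enough for the test, 10 shifted with a preset correlation of 0.01 and none with an estimated correlation, where the smallest adjusted p was 0.257. The number of arrays limits the precision of every value.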

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

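The tests of the repeated scans, of the size of the falls against the transfected share and of leukocytes, and of outlying scans in 8 of the 10 measures, were chosen after the results had been seen, and those of chromosomes and of the spread between scramble arrays before.

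Spots marked non-uniform, which no comparison uses, recurred within pairs of files. Mimic replicates 1 and 4 shared 27, replicates 2 and 5 shared 82, and replicates 3 and 6 shared 28. Scramble replicates 1 and 3 shared 24, and replicates 2 and 4 shared 70, against at most 2 in any other pair. Whether 1 array was scanned on 2 days cannot be told apart from these counts, since an array hybridised again would share its spots too, nor from the deviations of spots from the mean of their probe, where the lowest correlation of these pairs, 0.641, is not above the highest of all others, 0.690. Separate arrays of independent transfections are argued against, since the lowest correlation of these pairs, 0.984, lies above the highest of all others, 0.977. It cannot be told apart whether an array was hybridised again with other RNA, because the highest SD of log2 differences in a same-position pair, 0.390, is not below the lowest between different positions scanned on different days, 0.369. No biological explanation was tested.

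Many falls were larger than the stated transfection efficiency of 60% allows if untransfected cells kept their transcripts, which would leave 40% of the control and a fall of at most 2.5-fold. Of 530 genes that fell, 160 had a 95% limit beyond this, and 102 of these were well above background on at least 1 scan of each group. Some of the 102 were so on few mimic scans, such as Tnnc1 on 1 of 6. Myod1, Cdh15, Cfl2 and Acta2 were so on every scan. Their upper limits were −2.60, −1.54, −1.74 and −1.98, below the limit of −1.32 on the log2 scale. For such genes this argues against a change confined to the transfected 60% of cells. Another subline with other chromosome copies is argued against too, since the chromosome median farthest from that of all genes differed by 0.0864 on the log2 scale. Scramble cultures at another stage of differentiation cannot be told apart from the treatment. Over the differentiation list, the median per-gene difference of scramble array 2 minus scramble array 1 was −0.13, small beside the −3.14 between groups. But a stage common to both scramble arrays would leave them alike, so the bound set in advance tested nothing about it. A higher effective dose than the stated share and an effect on neighbouring cells stay open and untested. The microRNA's own action stays open too, tested only through seed matches in the probes (−0.34 in mean log2 difference) and not for the size of the falls.

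Cd68 and Cd14 rose while most other markers of the fixed leukocyte list were not well above background. Of the 14 other markers of that list, 3 were well above background on a mimic scan (Itgam, Csf1r and Cd3e), each of them on scramble scans too, so that 0 were so on mimic scans alone. The 11 on no scan include Lyz2, Tyrobp, Laptm5 and Coro1a, which are abundant in leukocytes, and this argues against leukocytes in the mimic cultures as the source. A change of these genes within the C2C12 cells is a hypothesis that stays open.

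Only 10 splits of the 5 arrays into 3 and 2 exist, too few for a share under 0.05. The real split, 1 of the 10, gave 1332 changed genes and the highest of the others gave 0. Each of the others mixes mimic and scramble arrays in at least 1 group. Any large difference between the real groups then enters the spread within groups and leaves few calls. The 0 is therefore no measure of what chance would give.

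The first scan of mimic array 2, mimic replicate 2, lay far from the other mimic scans in 4 of 10 measures: 58.2733% of its spots carried a substituted signal (next highest 47.367%), its lowest signal well above background was 121.793 (next 75.2722), and its column of the series matrix had a median of 356.3 (next 214.9) and 18807 values (next lowest 22741). Chance alone would place about 1 in 20 groups so, and 20 groups of scans were tested, of measures that are not independent; no scramble scan stood out. Without this scan 1157 genes changed, 680 higher and 477 lower, and without its array 672, 345 higher and 327 lower. Groups of 3 and 2 arrays are too small for that test.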

How the results depend on the processing

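The averaging of the 2 scans of a position was chosen after their positions were seen, in place of the 10 scans as separate samples, the fit chosen before the data were examined. The single scan days, the other percentile, the slide row, left-out arrays and the 10-scan fit with a random block were chosen after seeing the data too. No named gene or list past the threshold changed sign under any of the 36 settings that tested it. Of 73 called named genes 39 passed in all settings that tested them. Of 10 called lists 7 passed in all settings but the 2 other list tests. With an estimated correlation 0 of 10 lists passed, and with fry 7 lists passed. Of lists not past the threshold, the tricarboxylic acid cycle passed in 7 settings, fibroblast markers in 3, glycolysis in 2 and oxidative phosphorylation in 1. Changed genes fell from 1332 to 761 with scaling to the array median (483 higher, 278 lower), to 819 with array weights (468 and 351), to 810 with the slide row as a block (457 and 353) and to 407 without a filter (205 and 202), where 34607 genes were tested. All of these calls were at least 1.5-fold by the fitted difference. With normexp background the log2 difference of 27 of 73 called named genes was smaller by over 1.5 times. The second scan day alone gave 504 higher genes. The cause was not tested for the median, the weights and the second day. The slide row leaves 2 residual degrees of freedom. The 10 scans taken as separate samples gave 4154 changed genes (2517 higher, 1637 lower, 2916 at least 1.5-fold), which counts each array 2 times over. With scan date as a block they gave 4200 (2555, 1645 and 2926). With the replicate block they gave 2336 (1417, 919 and 2333), although the numbers are not said to pair the samples. While 0 of 4 scramble scans correlated best with their own number, each did so with a scan of its own day, which leaves the pairing undecided. Leaving out single scans or whole arrays gave 641 to 3671 changed genes (345 to 2460 higher, 275 to 1211 lower, 641 to 3671 at least 1.5-fold) and 7 to 14 lists. Only whole arrays moved the count by over 1.5 times: 641, 672 and 668 without mimic array 1, 2 and 3, with fewer samples, and 3671 without scramble array 1, where the lone scramble array is assumed to vary like the mimic arrays and the cause was not tested. Without scramble array 2 it was 969. Summed over the 5 left-out arrays, named genes lost a call 84 times and lists 3 times. A slide block was not run, since there is 1 slide, and neither were the seed searches with their alternatives. Signal over background limits 215 of the higher and 64 of the lower calls to a bound.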

Other observations

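The tests of gene families were chosen after the data had been seen, and that of seed matches before its result was.

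Families of genes that share the stem of their symbol were compared with all other genes, 321 families of at least 5 measured members in all. The clade B serpins, intracellular protease inhibitors, stood highest: 9 of 13 rose and none fell, with a median log2 difference of 1.28 (camera on the moderated statistics with a preset correlation of 0.01, adjusted p = 4.97e-15) and medians between 0.80 and 1.37 under the 6 other scalings, background corrections and deposited values tried. Besides Serpinb9f and Serpinb9g, Serpinb9e had 3.80 ± 0.29 (SE), Serpinb2 3.50 ± 0.34 and Serpinb7 3.14 ± 0.22, and several of these are close paralogs. CC chemokine genes rose in 4 of 7 cases with none lower (median 1.25, adjusted p = 2.75e-05), with Ccl9 at 2.43 ± 0.20, Ccl8 at 2.04 ± 0.20 and Ccl2 at 1.25 ± 0.21. Of 11 genes with the stem Ifi, many of them interferon-inducible, 6 rose and none fell (median 1.22, adjusted p = 0.000154). Of 5 genes with the stem Csf 2 rose, both for beta chains of cytokine receptors, Csf2rb at 3.13 ± 0.19 and Csf2rb2 at 2.71 ± 0.19 (adjusted p of the family 6.35e-06). The myosin light chain genes fell in 4 of 7 cases (median −1.58, adjusted p = 5.47e-10). The genes of this paragraph were chosen after their values were seen, and an estimated correlation was not tried for families. Only kept genes counted as members, and a gene could be kept through mimic scans alone. Serpinb9f and Serpinb9g were well above background on 6 mimic and 0 scramble scans. Families were not tried without a filter, so the medians and p-values of those that rose may overstate the rise. Their log2 differences are fitted values, with no bound given where a group was not well above background. Each family median given here kept its sign under the same alternatives. With normexp background the mean was 1.10 in place of 1.93 for the serpins and 0.73 in place of 1.38 for the stem Csf.

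A hypothesis written down before its test was that genes with a match to the miR-142-3p seed are lower with the mimic. Transcript sequences were not used here, so the search was limited to the 60 bases of each gene's probe, read in the sense of the transcript. The 32 genes whose probe holds ACACTAC differed from the other genes by −0.34 in mean log2 difference (two-sided permutation test with 100000 resamples, p = 0.00854, and 0.00854 after adjustment over 4 site types), with 6 called lower and 0 called higher. The 8-base site ACACTACA, in 14 genes, gave −0.60 (permutation p = 0.00429, adjusted 0.00741), CACTACA in 46 genes gave −0.30 (p = 0.00556, adjusted 0.00741) and the 6-base CACTAC in 113 genes gave −0.22 (p = 0.00113, adjusted 0.00452). The site sets are nested: the 14 genes with the 8-base site are among the 32, the 46 and the 113. The 4 tests are therefore not independent. These 14 genes had a mean log2 difference of −0.51, against −0.25 for the 32 that include them, so they carry much of the −0.34. The reverse complements GTAGTGT and GTAGTG gave 0.03 (permutation p = 0.735) and 0.00 (permutation p = 0.970). After removal of a trend with GC content the 7-base site ranked 100 from the lowest among 13819 words found in at least 10 probes, so other words went lower, GTGTGTG most of all. This is consistent with direct repression of part of the genes that fell, and says nothing about sites outside the probes; genes are not independent replicates.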
